A study of Mus musculus with 9 samples.

How the data were processed

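Total RNA was extracted from hindbrains of mouse embryos on embryonic day 9.5 with spin columns, and 500 ng per sample went into a stranded TruSeq library sequenced as single 75-nt reads on a NextSeq 500, per the labels' protocols. The strain was C57BL/6N, per the labels. The 3 genotypes of Zfp423 had 3 libraries each: wild-type littermates, the d9-20 allele and the d28-30 allele. The authors deposited 1 table of whole-number read counts per gene symbol for the 9 libraries, not normalized. STAR 2.5.3a, featureCounts and limma were used on the mm10 (GRCm38) build, per the submitters' processing notes. The annotation release, the strand setting of the counting, the treatment of reads that match several genes and any filter on reads are not given in the sources used here. Reads shared between near-identical genes or between a gene and its pseudogenes can therefore be split or lost in ways that these counts cannot show.

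The table has 48587 genes, no duplicated symbols, no line that names no gene and no column that belongs to no sample. Columns were matched to samples by title. Totals per library were 16903382 to 24216412 counts, and 3 counts, taken as a floor, correspond to 0.124 to 0.177 CPM. The square root of the common dispersion, the spread between libraries beyond counting error, was 0.110. For genes with few counts, such as Gmnc in the mutants, Slc38a8 in wt and Ccno in the mutants, counting error was larger than this value. Gene positions were taken from GENCODE M21 (GRCm38), in which 46384 of the symbols match exactly 1 gene. Positions were found for 97.1% of the genes tested.

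Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr for the 3 genotypes, which left 15695, and scaled with TMM factors. All 9 libraries were fitted in 1 quasi-likelihood model with genotype as the only factor, and contrasts were tested with glmQLFTest: d9-20 against wt, d28-30 against wt, d9-20 against d28-30, and any difference among the 3 genotypes. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. All adjusted p of single genes come from this model unless another tool is named. Standard errors of log2 fold changes are the absolute value divided by the square root of the F statistic. CPM values are per library after TMM scaling, and their means carry the SD over 3 libraries.

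The tests, the genes to be named, 36 gene lists and the alternatives were fixed before the data were examined. The lists cover regions of the neural tube, signalling pathways, neuronal and progenitor states, cilia, stress responses, cell types that a dissected hindbrain can include, sex-linked genes and genes that differ between C57BL/6 substrains. The 33 lists with at least 4 tested members that are not sex or substrain genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Ahsp, Deup1 and Dnai1, which were members of these lists, were not analysed here. Some genes belong to more than 1 list, such as Lmx1a, Msx2, Ebf2 and Ebf3. For each comparison the text names Zfp423, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 1 CPM and no overlap between the genotypes, and up to 4 members of each list past the threshold. Not every gene that meets this rule is given. Unnamed gene models, pseudogenes and sex-linked genes were left out of these. For lists on dorsal fate, choroid plexus and cilia without such a member, the 3 members with the smallest p were given, and where no gene passed, the 5 genes with the smallest p. Further genes are members of those lists or neighbours of Zfp423 and were singled out after their values were seen.

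The code was tested on simulated counts drawn from the libraries' means and sizes, with 200 genes changed in each mutant. The changed genes were picked above a minimum expected count, and all genes were drawn independently. Against wt, with 15531 genes in the fit, 67.2% of genes changed 1.5-fold and 92.5% of those changed 2-fold were recovered for d9-20, and the same shares for d28-30. False calls made up 6.52% of calls in d9-20 against wt, 5.46% in d28-30 against wt and 5.76% between the mutants. The effect of shared wt libraries was gauged with 50 simulations in which unchanged groups and wt were redrawn, each gene independently. Ratios of genes with 3 or fewer counts in a library were computed from counts summed per genotype, with exact (Clopper-Pearson) intervals from SciPy 1.17.1 that cover counting error only. Fisher's exact tests were two-sided.

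The titles number the libraries of each genotype as none, 1 and 2, without a statement that a number marks a litter, day or batch, and the fit had no replicate block. The correlation of same-numbered libraries' deviations from their genotype means was 0.133, 0.269 and 0.494 between d9-20 and wt, so that every pair was above 0.1, and the count with this block is given beside that result. It was -0.211, 0.196 and 0.243 between d28-30 and wt, and 0.0951, 0.162 and 0.229 between the mutants. The unnumbered libraries were taken as the third level of this block.

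Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, no filter on low counts, a filter of 1 CPM in 3 libraries, robust dispersion, the replicate block with 3 levels or on the 6 numbered libraries, a fit of only the genotypes compared, and each of the 9 libraries left out in turn. Covariates for Y-linked expression and for the erythroid share of counts, and counts of calls without genes within 20 Mb of Zfp423, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.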

Results

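The data were gene-level read counts from RNA sequencing of hindbrains dissected from mouse embryos on embryonic day 9.5. The embryos carried wild-type Zfp423 or 1 of 2 mutant alleles of this gene, which encodes a transcription factor with 30 zinc fingers. Per the labels, the d9-20 allele lacks exon 4, which removes zinc fingers 9 to 20 from the protein, and the d28-30 allele lacks exons 6 and 7, which removes zinc fingers 28 to 30. The wild-type (wt) libraries came from littermates, without a statement of which mutant line they belonged to. Each genotype had 3 libraries. The total count per library was 19217956 to 21657749 in wt, 19856714 to 21160036 in d9-20 and 16903382 to 24216412 in d28-30. Of 48587 genes in the table, 28389 had at least 1 count and 15695 were tested.

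Pearson's r of log CPM across genes lay between 0.986 and 0.993 within a genotype (median 0.990) and between 0.977 and 0.993 between genotypes (median 0.990), so that the genotypes did not stand apart on this measure. No 2 libraries of a genotype agreed within sampling noise, since chi-square per degree of freedom was at least 4.75. The d28-30 replicate 2 library stood apart from the rest, with chi-square per degree of freedom between 27.3 and 64.3 against the other 8 libraries, where no other pair was above 18.6, and with a mitochondrial share of counts of 2.07% beside 0.904% to 1.42%. Xist, the RNA that coats the inactive X chromosome of female cells, and the summed CPM of 4 Y-linked genes showed that the libraries differed in sex. In wt replicate 2, Xist was at 724 CPM beside 63.2 CPM of Y-linked genes, in d9-20 replicate 2 at 580 CPM beside 115 CPM, and in d28-30 replicate 2 at 1257 CPM beside 120 CPM, so these 3 libraries held RNA from female and male cells. Replicate 1 of d9-20 and of d28-30 had Xist at 1638 and 1505 CPM and Y-linked genes at 0.0504 and 0.0592 CPM, while the remaining 4 libraries had Y-linked genes at 170 to 206 CPM and Xist below 4 CPM. All wt libraries had Y-linked genes at 63.2 CPM or more, so sex was not balanced across the genotypes. The labels do not say that libraries of a genotype came from separate embryos or pools, so p-values measure only the spread between these samples. The 3 libraries of each mutant differed from each other in sex and so were not repeats of 1 RNA sample. The wt replicates 1 and 3 were alike in these genes. Their chi-square per degree of freedom was 13.5, beside 7.12 for wt replicates 1 and 2, which differed in sex. This argues against repeats of 1 RNA sample without settling it, since spread from library preparation was not measured. Libraries are named replicate 1 and 2 after the number in their titles, and the library of each genotype without a number is named replicate 3.

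Zfp423 itself was expressed at 108 ± 8.66 CPM in wt (SD, n = 3), 169 ± 22.3 CPM in d9-20 and 171 ± 12 CPM in d28-30. Its read count over the whole gene rose in both mutants, by a log2 fold change of 0.64 ± 0.10 (SE) in d9-20 (1.56-fold, adjusted p = 0.0360) and of 0.67 ± 0.10 in d28-30 (1.59-fold, adjusted p = 0.0257). All 3 libraries of each mutant lay above all 3 wt libraries. The call was lost in d9-20 (adjusted p up to 0.249) without any 1 library except d28-30 replicate 2, and in d28-30 (adjusted p up to 0.173) without any 1 library except d9-20 replicate 3 and d28-30 replicate 2, with log2 fold changes between 0.53 and 0.73. Between the mutants the log2 difference was -0.02 ± 0.10 (adjusted p = 0.937). The gene lies at positions 87661810 to 87959595 of chromosome 8 (GRCm38). In the transcript Zfp423-202 of 4907 nt, exon 4 spans 87780199 to 87783413 and has 3215 nt (65.5% of the transcript), while exons 6 and 7 together have 248 nt (5.05%). The d9-20 count lay above wt and was close to that of d28-30, which by its label lacks 5.05%. Loss of all of exon 4 (65.5% of the transcript) would lower the count at an unchanged number of transcripts. Loss of only a part of exon 4 would lower it less, and how much of exon 4 is missing from the RNA is not known here. The fold changes are therefore of reads over the whole gene and not of transcript number, and since the table has no counts per exon, neither the transcript number nor the deletion itself could be read from it.

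**Figure D1:**
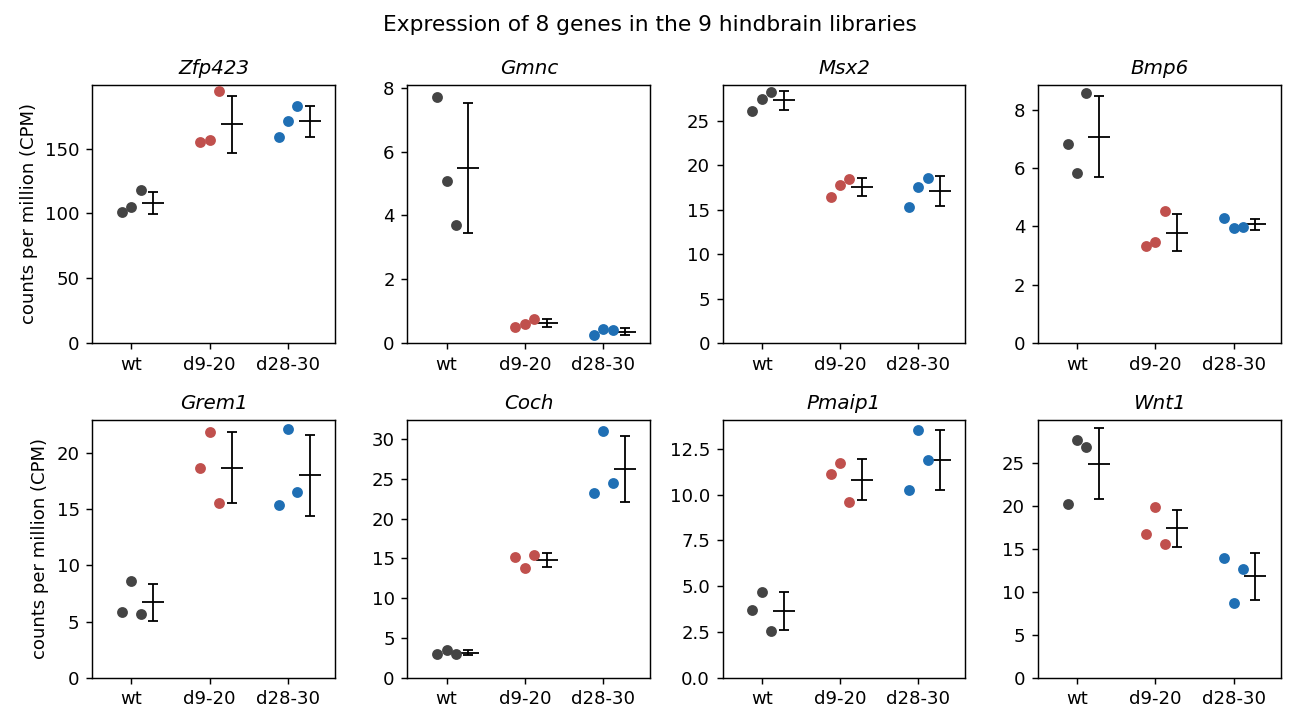
Scaled read counts (CPM, vertical axes from 0) of 8 genes in each of the 9 libraries, in the order replicate 1, 2 and 3 from left to right within a genotype, with the mean and SD (n = 3) to the right of the points. Zfp423, Grem1, Coch and Pmaip1 lie higher in every mutant library than in every wt library, and Gmnc, Msx2, Bmp6 and Wnt1 lower, where Bmp6 and Wnt1 did not pass the threshold over all genes.

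In the d9-20 hindbrains, Gmnc, Msx2 and Mri1 fell and 23 genes rose against wt, among them Coch, Pmaip1 and Grem1. Gmnc encodes the geminin-like coiled-coil protein that starts the programme of multiciliated cells. It fell by 3.13 ± 0.31 on the log2 scale (8.77-fold lower, adjusted p = 0.00404), from 5.50 ± 2.04 CPM (SD, n = 3) to 0.621 ± 0.124 CPM. Its counts were 168, 101 and 72 in the wt libraries and 10, 12 and 16 in the d9-20 libraries. It spans 26913553 to 26991652 on chromosome 16. Msx2, which encodes a homeodomain factor of the dorsal midline induced by BMP signals, fell by 0.63 ± 0.10 (adjusted p = 0.0360), from 27.3 ± 1.09 to 17.6 ± 1.03 CPM. The third gene that fell was Mri1, which encodes an enzyme of methionine salvage, with a log2 fold change of -0.88 ± 0.11 (adjusted p = 0.0128).

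Of the 23 genes that rose in d9-20, Coch, which encodes the extracellular matrix protein cochlin, rose by 2.24 ± 0.14 (4.72-fold, adjusted p = 6.08e-05), from 3.13 ± 0.295 to 14.8 ± 0.835 CPM (SD, n = 3). Slc38a8, which encodes an amino acid transporter, rose from 11 counts over the 3 wt libraries to 129 over the 3 d9-20 libraries, a ratio of 11.7 per total count with an exact 95% interval from 6.33 to 24.0 (adjusted p = 0.0332). Pmaip1, which encodes the pro-apoptotic BH3-only protein NOXA, rose 2.97-fold, and Grem1, which encodes a secreted antagonist of BMPs, rose 2.79-fold. Des and Flnc, which encode the muscle proteins desmin and filamin C, rose 2.46-fold and 1.98-fold. Bcas1 rose 3.99-fold, and the synaptic genes Nptx2 and Rimbp2 rose 2.12-fold and 2.02-fold. The adjusted p of these 7 genes lay between 0.00466 and 0.0172. Calls were lost without wt replicate 1 (Pmaip1, Grem1, Bcas1, Flnc, Nptx2 and Slc38a8), wt replicate 2 (Slc38a8), wt replicate 3 (Grem1, Bcas1, Flnc, Rimbp2, Mri1 and Slc38a8), d9-20 replicate 1 (Pmaip1, Grem1, Bcas1 and Mri1), d9-20 replicate 2 (Pmaip1, Grem1, Bcas1, Rimbp2, Mri1 and Slc38a8), d9-20 replicate 3 or d28-30 replicate 3 (Slc38a8), with adjusted p up to 0.0863 for Pmaip1, 0.150 for Bcas1, 0.151 for Grem1 and 0.249 for Slc38a8. With the erythroid share of counts as a covariate, all of these genes except Coch and Nptx2 missed the threshold, while Gmnc passed.

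Of the 15695 genes tested in d9-20 against wt with edgeR's quasi-likelihood test, 26 passed an adjusted p of 0.05, 23 of them higher and 3 lower. In all 26, the 3 d9-20 libraries did not overlap the 3 wt libraries, which held for 11.2% of all genes tested where chance gives 10%. The count of calls rested on single libraries: it was 6 without wt replicate 3, 7 without wt replicate 1 or d9-20 replicate 2, 9 without d9-20 replicate 1, 15 to 17 without wt replicate 2, d9-20 replicate 3 or d28-30 replicate 3, and 93 without d28-30 replicate 2. It was 55 with the number in the titles as a block, while Gmnc and Coch passed with each library left out in turn. Msx2 was lost (adjusted p up to 0.215) without any 1 library except d28-30 replicate 1 or 2. It was lost also with the Y-linked covariate, the erythroid covariate and the block on numbered libraries, in 10 of 20 settings (adjusted p up to 0.240).

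The roof plate and dorsal midline list was lower in d9-20 (12 members tested, 10 with a negative log2 fold change, median -0.27). Camera gave an adjusted p of 3.99e-08, and the adjusted p = 0.354 with an estimated correlation. Msx2 fell over all genes tested, and 5 members passed when adjusted over the list alone, all of them lower. These were Msx2, the BMP ligand gene Bmp6 (-0.90 ± 0.17), the roof plate regulator Lmx1a (-0.60 ± 0.12), Rspo1 (-0.63 ± 0.20), which encodes an enhancer of WNT signalling, and the WNT ligand gene Wnt1 (-0.52 ± 0.18). In the list of the multiciliation programme and motile cilia, 15 of 19 members tested had a negative value (median -0.18, camera adjusted p = 5.15e-06, and adjusted p = 0.354 with an estimated correlation). Gmnc fell over all genes tested. Adjusted over the list alone, Gmnc and Ccno passed, both lower. Ccno, a gene of centriole amplification, had 70 counts in wt and 11 in d9-20, a ratio of 6.38 per total count (exact 95% interval 3.35 to 13.4, adjusted p = 0.117 over all genes tested). Foxj1, which encodes a regulator of motile cilia, had a log2 fold change of 0.24 ± 0.25.

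Lists of other cell types also differed between d9-20 and wt. All 11 erythroid genes tested were lower (median -0.59, camera adjusted p = 2.40e-12, and adjusted p = 0.354 with an estimated correlation), 0 of them past the threshold over all genes tested and 7 adjusted over the list alone. The erythroid share of counts was 0.365% to 0.418% in the d9-20 libraries and 0.410% to 0.797% in wt. Early neuronal genes were lower in 20 of 21 members (median -0.23, adjusted p = 3.35e-08, and adjusted p = 0.395 with an estimated correlation), and macrophage genes in 8 of 10 (median -0.59, adjusted p = 2.49e-05, and adjusted p = 0.354 with an estimated correlation). Neural crest genes were higher in 11 of 14 members (median 0.18, adjusted p = 5.36e-05, and adjusted p = 0.354 with an estimated correlation) and endothelial genes in 13 of 15 (median 0.15, adjusted p = 0.000128, and adjusted p = 0.354 with an estimated correlation). No member of these 4 lists passed over all genes tested, and 1 macrophage gene, Csf1r, passed adjusted over the list alone (-1.10 ± 0.28, 2.63 ± 0.630 CPM in wt and 1.23 ± 0.364 CPM in d9-20).

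Smaller shifts were found in 3 further lists. Targets of BMP and TGF-beta were lower in 12 of 15 members (median -0.10, adjusted p = 0.0391, and adjusted p = 0.391 with an estimated correlation). Msx2 was the member past the threshold over all genes tested, and adjusted over the list alone 1 gene was higher and 1 lower. Genes of dorsal progenitors and the rhombic lip were lower in 14 of 18 members (median -0.12, adjusted p = 0.00487, and adjusted p = 0.444 with an estimated correlation). None of these 18 passed over all genes tested and 1, Olig3, passed adjusted over the list alone. Olig3, a marker of dorsal hindbrain progenitors, was at 21.6 ± 4.15 CPM in d9-20 and 32.0 ± 1.47 CPM in wt (SD, n = 3, adjusted p = 0.146), Barhl1 had a log2 fold change of -0.99 ± 0.40 and Zic4 of -0.48 ± 0.20. The list of EBF factors and ZFP423 relatives, which holds Zfp423, was called higher (adjusted p = 0.00848, and adjusted p = 0.391 with an estimated correlation) with 3 members above 0, 3 below and a median of 0.03. Zfp423 rose over all genes tested, and adjusted over the list alone Zfp423 and Ebf4 (0.58 ± 0.14) passed. The choroid plexus epithelium list was not called (13 members tested, median 0.00, mean -0.05, adjusted p = 0.305), and 0 of its members passed either way. Slc4a5, Cdo1 and Cldn1 had values of -0.55 ± 0.21, -0.22 ± 0.09 and -0.38 ± 0.19. Of the 33 lists tested, 10 were called, and 0 were called with an estimated correlation or by fry's directional test, while fry's test for change in either direction called 10. With the erythroid share of counts as a covariate, chosen after the data were seen, 4 lists were called, among them roof plate, and the calls of the multiciliation, erythroid, macrophage and neural crest lists and of the 3 lists of smaller shifts were lost. Of the latter, that of dorsal progenitors was lost also without wt replicate 1 (adjusted p = 0.0589) or d9-20 replicate 1 (0.118), that of BMP and TGF-beta targets without wt replicate 2 (0.132), wt replicate 3 (0.0915) or d9-20 replicate 1 (0.252), and that of EBF factors without wt replicate 2 (0.162) or d9-20 replicate 3 (0.140). Limma-voom ended the calls of BMP and TGF-beta targets and of EBF factors, the latter lost also with the block on numbered libraries. The Y-linked covariate ended those of dorsal progenitors and of BMP and TGF-beta targets.

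**Figure D2:**
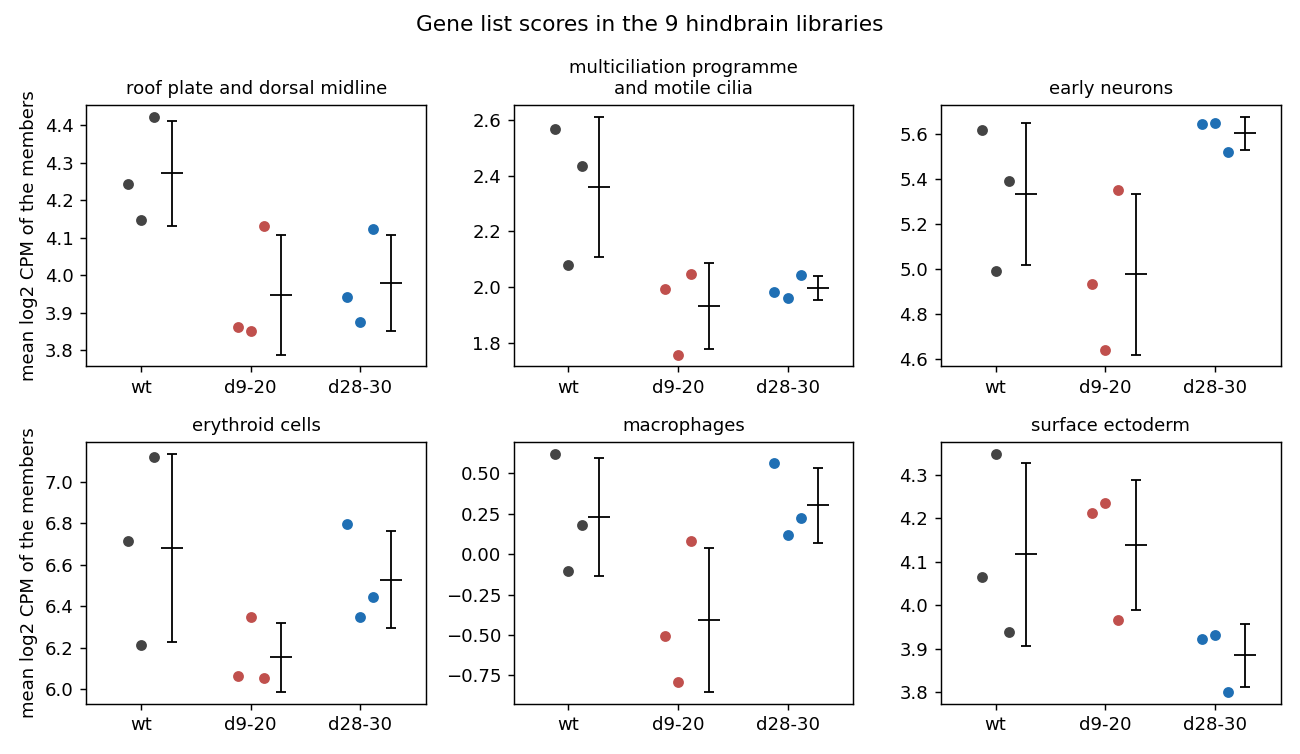
Mean log2 CPM of the members of 6 gene lists (vertical axes, which do not start at 0) in each of the 9 libraries, in the order replicate 1, 2 and 3 within a genotype, with the mean and SD (n = 3). Roof plate and multiciliation scores lie lower in every mutant library than in every wt library, while the early neuron score of the d9-20 libraries lies below that of the d28-30 libraries. The scores are means: in d28-30, 10 of 19 multiciliation members lay below 0 against wt, with a median log2 fold change of -0.01.

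In the d28-30 hindbrains, Gmnc also fell, by 3.91 ± 0.34 on the log2 scale (15-fold lower, adjusted p = 0.000995), to 0.352 ± 0.101 CPM (SD, n = 3) and counts of 4, 10 and 9. Msx2 fell by 0.67 ± 0.10 to 17.1 ± 1.70 CPM (adjusted p = 0.0226). Coch rose by 3.07 ± 0.14 (8.40-fold, adjusted p = 3.78e-06), from 3.13 ± 0.295 to 26.3 ± 4.17 CPM. Stk32a, which encodes a serine/threonine kinase, rose 5.53-fold (adjusted p = 0.00128), from 1.28 ± 0.218 to 7.10 ± 0.265 CPM. Slc38a8 had 143 counts over the 3 d28-30 libraries beside 11 in wt, a ratio of 12.5 per total count with an exact 95% interval from 6.77 to 25.6 (adjusted p = 0.0225).

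Pmaip1 rose 3.27-fold in d28-30 (adjusted p = 0.00477), Grem1 2.70-fold (adjusted p = 0.0213) and Nptx2 2.27-fold (adjusted p = 0.00353). The WNT ligand gene Wnt3 rose 2.23-fold, from 10.3 ± 1.09 to 23.0 ± 1.23 CPM (SD, n = 3, adjusted p = 0.0213). Fam129c and Zfp868, which lie 16.2 and 18.2 Mb from Zfp423 on chromosome 8, rose 2.17-fold and 1.98-fold, with the same adjusted p of 0.0213. Mri1 fell by 1.05 ± 0.11 (adjusted p = 0.00353). This gene lies 3.56 Mb from Zfp423. Wnt1 missed the threshold with a log2 fold change of -1.09 ± 0.18 (adjusted p = 0.0527). It was at 11.8 ± 2.73 CPM in d28-30 and 24.9 ± 4.08 CPM in wt, and was singled out after its values were seen. The call of Wnt3 was lost without wt replicate 1, 2 or 3 or d28-30 replicate 1 or 3 (adjusted p up to 0.139), and that of Slc38a8 without the same 5 libraries (up to 0.134). That of Grem1 was lost without wt replicate 1 or 3, d9-20 replicate 1 or d28-30 replicate 3 (up to 0.118), and those of Fam129c and Zfp868 without wt replicate 2 or 3, d9-20 replicate 1 or 2 or d28-30 replicate 3 (up to 0.139), for Fam129c also without wt replicate 1 or d28-30 replicate 1.

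Against wt, 25 of 15695 genes passed in d28-30 with edgeR's quasi-likelihood test, 21 higher and 4 lower. All 25 separated the 3 d28-30 from the 3 wt libraries, as did 12.8% of all genes tested where chance gives 10%. The count lay between 10 and 16 without wt replicate 3 (10), d28-30 replicate 3 (11), wt replicate 1 (12), wt replicate 2 (14), d28-30 replicate 1 (14), d9-20 replicate 1 (15) or d9-20 replicate 2 (16). Gmnc, Coch, Stk32a and Pmaip1 passed with each library left out in turn, and Msx2 was lost (adjusted p up to 0.126) without any 1 library except d9-20 replicate 3 or d28-30 replicate 2. Msx2 was lost also with the block on numbered libraries and a fit of only the genotypes compared, in 9 of 20 settings (adjusted p up to 0.2705).

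The roof plate and dorsal midline list was lower in d28-30 as well (9 of 12 members below 0, median -0.09, camera adjusted p = 2.21e-05, and adjusted p = 0.859 with an estimated correlation). Msx2 fell over all genes tested, and 5 members passed adjusted over the list alone, all of them lower. They were Wnt1, Msx2, Bmp6 (-0.80 ± 0.17), Rspo1 (-0.72 ± 0.20) and Lmx1a (-0.34 ± 0.12). In the multiciliation list, 10 of 19 members were below 0 (median -0.01, mean -0.45, camera adjusted p = 0.0179, and adjusted p = 0.888 with an estimated correlation). Gmnc fell over all genes tested, and Gmnc and Ccno passed adjusted over the list alone. Ccno had 70 counts in wt and 5 in d28-30, a ratio of 14.6 per total count (exact 95% interval 5.96 to 46.3, adjusted p = 0.0546 over all genes tested). Foxj1 had a log2 fold change of 0.30 ± 0.25.

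Early neuronal genes were higher in d28-30 in 19 of 21 members (median 0.25, adjusted p = 0.000104, and adjusted p = 0.965 with an estimated correlation), and 0 passed over all genes tested or adjusted over the list alone. Neurod4 had a value of 0.63 ± 0.18 and Neurod1, another proneural gene, of 0.60 ± 0.18. All 6 EBF factors and ZFP423 relatives were higher (median 0.28, adjusted p = 1.91e-05, and adjusted p = 0.673 with an estimated correlation). Zfp423 rose over all genes tested, and Zfp423 and Ebf4 (0.44 ± 0.14) passed adjusted over the list alone. Surface ectoderm genes were lower in 10 of 12 members (median -0.27, adjusted p = 0.00372, and adjusted p = 0.888 with an estimated correlation), with 0 past the threshold over all genes tested or adjusted over the list alone. The simple epithelial keratin genes Krt8 and Krt18 had values of -0.45 ± 0.17 and -0.49 ± 0.18.

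The choroid plexus epithelium list was not called in d28-30 (13 members tested, median -0.04, adjusted p = 0.875), nor was that of dorsal progenitors and the rhombic lip (18 members tested, median -0.01, mean 0.06, adjusted p = 0.954), with 0 members past the threshold over all genes tested or adjusted over the list alone. Cldn2 had a log2 fold change of 0.71 ± 0.28, Igfbp2 of -0.34 ± 0.17 and Cldn1 of -0.38 ± 0.19. Among dorsal genes, Olig3 had -0.46 ± 0.12, Lhx2 1.04 ± 0.48 and Zic1 0.13 ± 0.08. In total 5 of 33 lists were called, 0 with an estimated correlation and 0 by fry's directional test, and fry's test for change in either direction called 8. Of these calls, that of early neurons was lost without wt replicate 2 (adjusted p = 0.282), that of surface ectoderm without wt replicate 2 (0.292) or d28-30 replicate 3 (0.0736), and that of multiciliation without wt replicate 1 (0.156), d28-30 replicate 1 (0.0613), 2 (0.0508) or 3 (0.0736). The multiciliation call was lost also with limma-voom, the filter of 1 CPM in 3 libraries and the erythroid covariate, and passed in 12 of 19 settings. Without wt replicate 3 or d28-30 replicate 2, 8 and 9 lists were called.

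The mutants were also compared with each other, to ask whether the alleles left different transcriptomes. No gene passed in d9-20 against d28-30 with edgeR's quasi-likelihood test (0 of 15695, smallest adjusted p = 0.0630). An unadjusted p under 0.05 was found for 1504 genes (9.58%), limma-voom called 0 genes and DESeq2 called 79. Without d28-30 replicate 2 the count was 4 and without wt replicate 3 it was 1. The 3 libraries of each mutant separated completely in 16.8% of genes where chance gives 10%. The smallest p-values belonged to Zfp868 (23.3 ± 1.65 CPM in d9-20 and 50.6 ± 8.94 CPM in d28-30, SD, n = 3, log2 fold change -1.12 ± 0.14) and to Gm7809, a processed pseudogene on chromosome 17 whose reads may be shared with its parent gene (-3.57 ± 0.45). Fam129c (-1.17 ± 0.16, adjusted p = 0.0855), Coch (-0.83 ± 0.12, adjusted p = 0.121) and Fgfbp3 (-0.57 ± 0.09, adjusted p = 0.144) came next. In simulated counts with the same group sizes, the test recovered 74.6% of genes changed 1.5-fold and 96.3% of genes changed 2-fold between the mutants. Changes were set only in genes above a minimum expected count, and genes were drawn independently. These shares do not bound what was missed here, and Zfp868, 2.17-fold lower in d9-20, did not pass.

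Early neuronal genes were lower in d9-20 than in d28-30 in all 21 members (median -0.62, camera adjusted p = 1.70e-19, and adjusted p = 0.526 with an estimated correlation). None passed over all genes tested, and 12 passed adjusted over the list alone, among them Map2 (-0.71 ± 0.14), Elavl4 (-0.81 ± 0.17), Neurod4 (-0.84 ± 0.18) and Dcx (-1.02 ± 0.29). Macrophage genes (9 of 10 lower, median -0.84, adjusted p = 0.000392) and erythroid genes (11 of 11 lower, median -0.35, adjusted p = 0.000236) were lower in d9-20 too, each with an adjusted p = 0.526 with an estimated correlation. In these lists 0 genes passed over all genes tested, and 2 and 1 passed adjusted over the list alone. The erythroid share of counts was 0.425% to 0.650% in the d28-30 libraries, above the highest d9-20 library. With this share as a covariate, chosen after the data were seen, 2 lists were called between the mutants in place of 13.

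Neural crest genes were higher in d9-20 than in d28-30 in 10 of 14 members (median 0.24, adjusted p = 0.00561, and adjusted p = 0.526 with an estimated correlation). None passed over all genes tested, and Sox10 (0.50 ± 0.11), Erbb3 (0.45 ± 0.10) and Foxd3 (0.54 ± 0.15) passed adjusted over the list alone. Surface ectoderm genes were higher in 10 of 12 members (median 0.34, adjusted p = 0.000826, and adjusted p = 0.526 with an estimated correlation) and genes of the isthmus and midbrain in 14 of 19 (median 0.18, adjusted p = 0.00421, and adjusted p = 0.526 with an estimated correlation), with 0 members of either past the threshold over all genes tested or adjusted over the list alone. Fgf8, the organising signal of the isthmus, had a value of 0.51 ± 0.17, and Egr2, a regulator of rhombomere identity outside this list, of 1.17 ± 0.33. The roof plate list did not separate the mutants (median 0.04, mean -0.03, adjusted p = 0.913). Its members with the smallest p were Wnt1 (0.57 ± 0.18), Rspo3 (-0.60 ± 0.25) and Lmx1a (-0.26 ± 0.12). Neither the choroid plexus list (median -0.06, adjusted p = 0.691) nor the multiciliation list (median -0.06, adjusted p = 0.434) was called. In the former, Cdo1, Otx2 and Clic6 had values of -0.26 ± 0.09, -0.21 ± 0.10 and 0.26 ± 0.13, and in the latter Dnah11, Tppp3 and Tekt1 had -0.57 ± 0.21, -0.50 ± 0.22 and -0.27 ± 0.13. In these 3 lists 0 members passed over all genes tested or adjusted over the list alone. Of 33 lists, 13 were called, 8 higher and 5 lower in d9-20, and 0 were called with an estimated correlation or by fry's directional test, and 6 were called without d28-30 replicate 1.

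The genes called in both mutants were compared to ask whether either allele came with the same changes against wt. Of the 26 genes called in d9-20 and the 25 called in d28-30, 15 were called in both in the same direction and 0 in opposite directions. The 12 shared higher genes included Coch, Slc38a8, Pmaip1, Grem1, Nptx2, Rimbp2, Flnc, Lgi2, Pla2g7 and Zfp423, and the 3 shared lower genes were Gmnc, Mri1 and Msx2. The number shared was 5 without wt replicate 1, wt replicate 3, d9-20 replicate 1 or d9-20 replicate 2, 9 without d28-30 replicate 3 and 25 without d28-30 replicate 2. Independent lists of these sizes would share 0.0308 higher and 0.000765 lower genes. In 50 simulations of unchanged groups against simulated wt libraries common to both, 0 genes were shared, which says little because unchanged groups are seldom called. Across all genes tested, which are not independent replicates, the log2 fold changes of the mutants had a Pearson's r of 0.446, below that of simulated unchanged groups, 0.501 ± 0.0166 (SD). Their covariance was 0.0319 beside 0.0243 ± 0.00132 in the simulations, a difference of 0.00760. The simulations drew each gene independently, without the variation across many genes seen between the real libraries. Their SD may therefore understate the real spread. The 3 wt libraries could not be split into separate sets of 2 for the mutants, so part of the excess may come from the shared controls. Of the genes called in 1 mutant, 11 were called in d9-20 and 10 in d28-30, and none of these 21 genes passed the direct test between the mutants, in which the smallest adjusted p was 0.0630.

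**Figure D3:**
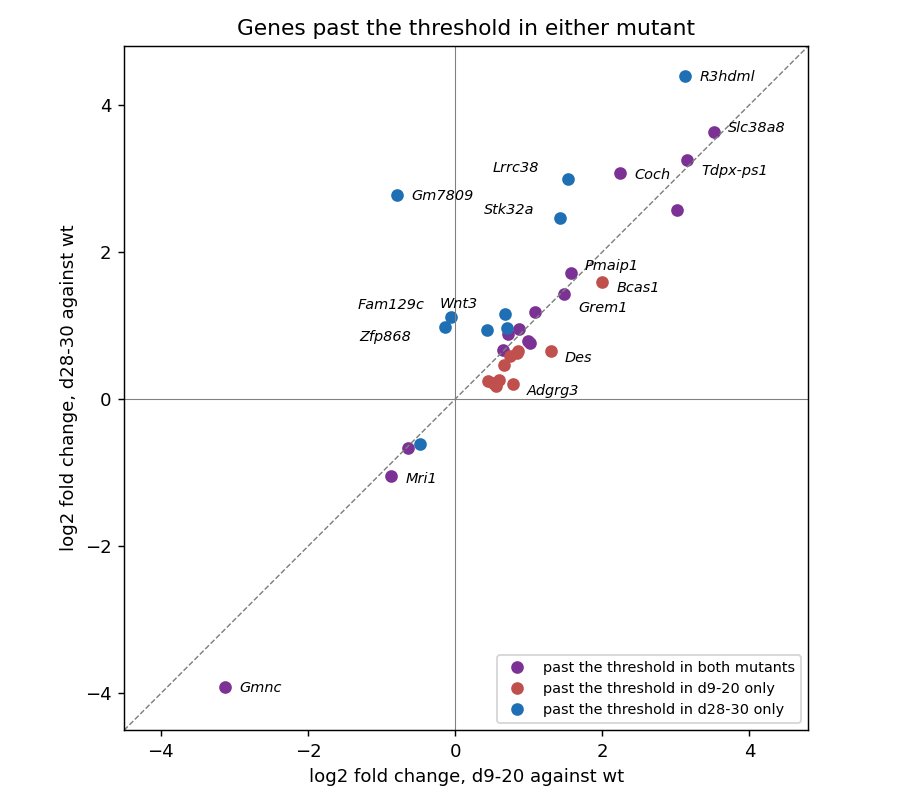
Log2 fold change against wt in d9-20 (horizontal axis) and d28-30 (vertical axis) of the 36 genes past an adjusted p of 0.05 in either comparison, coloured by where they passed, with the dashed line marking equal change. The 15 genes past the threshold in both lie on the same side of 0 in both, with Gmnc at -3.13 and -3.91.

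Genes near Zfp423 on chromosome 8 were over-represented among the calls. Within 20 Mb of Zfp423 lay 363 of 14672 autosomal genes tested (2.47%, Zfp423 left out) but 3 of the 24 autosomal calls in d9-20 (odds ratio 5.67, Fisher's exact test, two-sided, p = 0.0207) and 5 of the 24 in d28-30 (odds ratio 10.5, p = 0.000260 in Fisher's exact test). They included Mri1 and Adgrg3 in d9-20, and Mri1, Zfp868 and Fam129c in d28-30. Slc38a8 lies on the same chromosome, 31.7 Mb from Zfp423. This test was chosen after the called genes were seen.

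**Figure D4:**
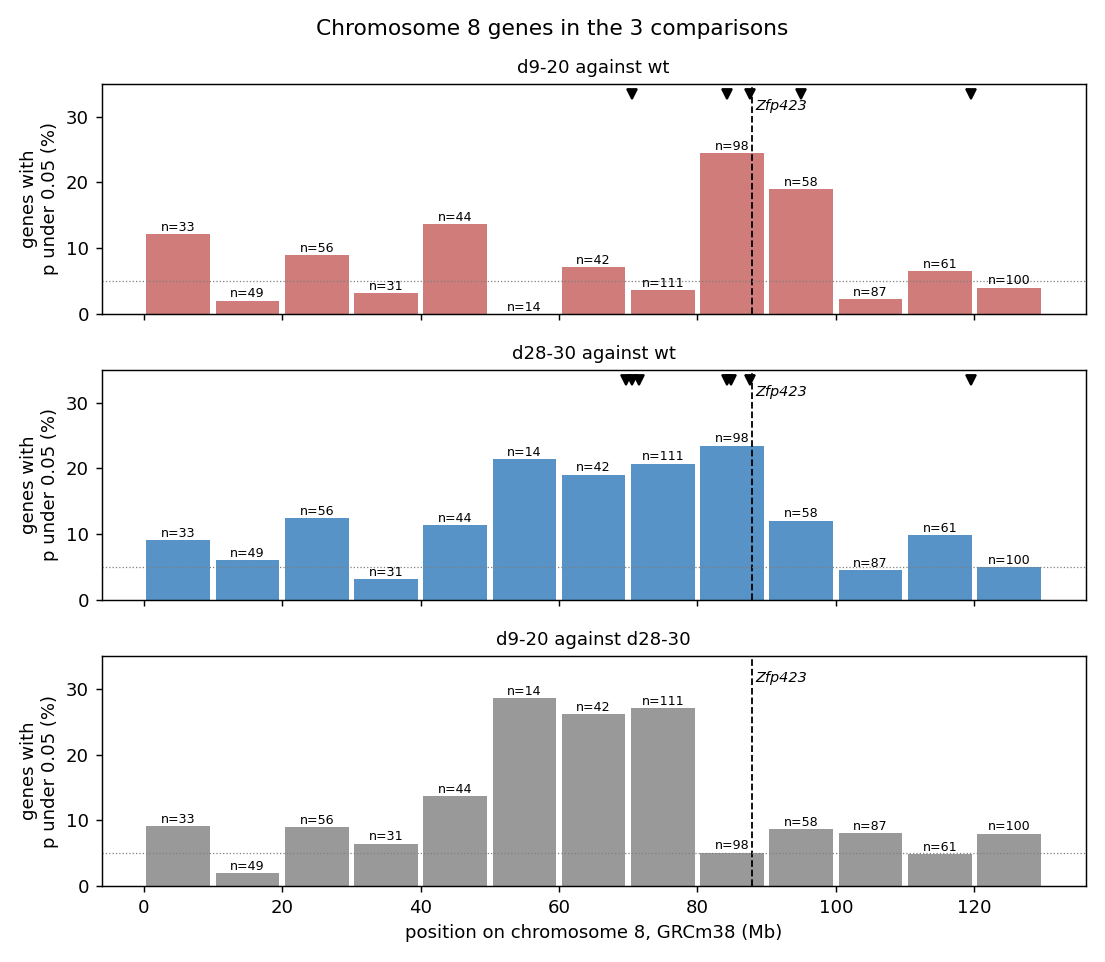
Share of tested genes with an unadjusted p under 0.05 (vertical axis, %) in 10-Mb bins of chromosome 8 (horizontal axis, GRCm38, Mb) for the 3 comparisons, with the number of genes per bin above each bar, a dotted line at 5%, triangles at genes past an adjusted p of 0.05 (Zfp423 among them) and a dashed line at Zfp423. In d9-20 the bins from 80 to 100 Mb reach 24.5% and 19%, and in d28-30 the bins from 60 to 90 Mb lie between 19% and 23.5%.

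The test for any difference among the 3 genotypes called 26 genes with edgeR's quasi-likelihood test (1299 genes at an unadjusted p under 0.05), with a smallest adjusted p of 1.38e-05. The count was 10 without wt replicate 1, 13 without wt replicate 3, 15 without d9-20 replicate 2, 14 without d28-30 replicate 1 and 62 without d28-30 replicate 2.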

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

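The test of linked variants, the test of a short-range effect and the comparison of Gmnc with the roof plate list were chosen after the results were seen, as were the covariates, while the regroupings of the libraries and the test of early neuronal genes were chosen before. The direct test between the mutants singled out 13 gene lists, whose median log2 differences are given as d9-20 minus d28-30. All 13 calls are lost with an estimated correlation (smallest adjusted p = 0.526), and 2 lists were called with the erythroid share of counts as a covariate. Lower in d9-20 were early neurons (-0.62), macrophages (-0.84), erythroid cells (-0.35), EBF factors and ZFP423 relatives (-0.18) and dorsal progenitors and the rhombic lip (-0.13). Higher in d9-20 were surface ectoderm (0.34), neural crest (0.24), isthmus and midbrain (0.18), endothelium (0.14), rhombomere regulators (0.14), hindbrain Hox genes of paralog groups 1 to 4 (0.14), hypoxia and glycolysis (0.12) and immediate early genes (0.068).

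Gmnc fell far more than the genes of the roof plate and dorsal midline list. A smaller share of dorsal midline tissue in the mutant dissections would lower the roof plate genes by about as much as Gmnc. This holds if the RNA of both came from that tissue alone, and where Gmnc is expressed cannot be read from bulk counts. The median of the 12 roof plate members was -0.27 in d9-20 (SD over members 0.331) and -0.091 in d28-30 (SD 0.425), while Gmnc had -3.13 and -3.91, a gap of 8.64 and 8.98 SD. This SD is the spread among members and not an error. Members lay between -0.90 and 0.16 in d9-20 and between -1.09 and 0.24 in d28-30. The gap argues against lost midline tissue as the whole cause only if the members are expressed mainly there, which was not tested. It stays open whether a small set of cells that express Gmnc is missing, or whether they are present and express less of it, since bulk counts cannot part these. A direct effect of the altered ZFP423 on Gmnc may account for it and was not tested.

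Called genes gathered on chromosome 8 around Zfp423. Among genes that did not pass the threshold, those within 20 Mb of Zfp423 more often had an unadjusted p under 0.05 than other autosomal genes, with 10.8% against 5.75% in d9-20 (odds ratio 1.99, 95% interval 1.38 to 2.81, Fisher's exact test p = 0.000230) and 15.6% against 7.68% in d28-30 (odds ratio 2.23, 1.63 to 3.00, p = 7.06e-07), as variants carried along with the mutant alleles would need. Fisher's test treats neighbouring genes as independent, so these p-values may overstate the excess. In windows of equal width along the autosomes, the highest share in a window holding Zfp423 was 12.5% in d9-20 and 19.7% in d28-30. The highest in windows without it, chromosome 8 included, was 11.3% and 17.3%. Between the mutants the former was 18.9% and the latter 24.2%. Windows without Zfp423 could overlap the 20 Mb around it, so they are not a separate benchmark. Between the mutants, the chromosome 8 bins from 60 to 70 Mb and from 70 to 80 Mb had 26.2% and 27.0%. Within 20 Mb of Zfp423 the share between the mutants was 14.6% against 9.49% elsewhere (odds ratio 1.63, 1.19 to 2.20, Fisher's exact test p = 0.00206). A short-range effect of the deletions is argued against as the whole cause, since the excess among genes not past the threshold was also found 2 to 20 Mb away (odds ratio 1.86, 1.26 to 2.66, Fisher's exact test p = 0.00150 in d9-20, and 2.21, 1.60 to 2.99, p = 1.90e-06 in d28-30), while for part of it, such as the 4 of 16 genes within 2 Mb with a p under 0.05 in d9-20, it stays open. Linked variants are therefore a candidate explanation for the changes of Mri1, Zfp868, Fam129c and Adgrg3, although these values cannot exclude that some of them respond to ZFP423. The labels name only the strain C57BL/6N, and how the alleles were made is not given in the sources used here. Whether variants near Zfp423 differ between the genotypes is not known. Such differences could be read from the sequences of the reads, which the counts do not hold.

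Early neuronal genes were lower in d9-20 than in d28-30. Their mean log2 CPM was 4.98 ± 0.357 in d9-20, 5.6 ± 0.0738 in d28-30 and 5.33 ± 0.318 in wt (SD, n = 3), and every d28-30 library lay above every d9-20 library. The difference of -0.63 between the mutants was smaller than the range of 0.71 among the 3 d9-20 libraries, so differences in stage or dissection between libraries may account for it, and these cannot be told apart from an effect of the alleles with 3 libraries each. The erythroid and macrophage lists differed in the same direction.

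Regrouping the libraries tested whether chance could give as many calls. For d9-20 against wt, 1 of the 10 splits of the 6 libraries gave as many genes as the real one (26, highest other 0), and for d28-30 against wt 1 of 10 did (25, highest other 0). Between the mutants the real count was 0, so all 10 splits had to give as many and this comparison tests nothing (highest other 0). With 10 splits the share cannot fall under 0.05. For the 3 genotypes together, 2 of 100 splits drawn from 280 gave as many genes as the real 26, 1 of them the real grouping. This share is under 0.05, but regrouping treats the libraries as exchangeable, although same-numbered libraries of d9-20 and wt were correlated. The number of calls alone did not single out genotype, since the highest other split called 46. That split set wt replicate 1 with d28-30 replicates 1 and 2, wt replicate 2 with d9-20 replicates 1 and 2, and replicate 3 of all 3 genotypes together, while the split by title number alone called 0 genes. A further split that kept the d28-30 libraries together and set wt replicate 2 with d9-20 replicates 1 and 2 called 25. The libraries thus hold structure besides genotype.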

How the results depend on the processing

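The covariates and the omission of genes within 20 Mb of Zfp423 were chosen after the results were seen. The counts of genes called in d9-20 vs wt (26) and d28-30 vs wt (25) stayed within 1.5 times under limma-voom, RLE factors, a filter of 1 CPM in 3 libraries, robust dispersion and without genes within 20 Mb. With DESeq2 they were 122 and 95, without a filter on low counts 148 and 98, and with the replicate block 55 and 48, which included all 26 and all 25 genes. Fits of only the 2 genotypes compared gave 40 and 12, with fewer libraries behind the dispersions. The block on numbered libraries gave 18 in d9-20 vs wt, 9 of them among the 26, and 11 in d28-30 vs wt, all among the 25, and the Y-linked and erythroid covariates gave 16 and 7 in d9-20 vs wt. Between the mutants (0) DESeq2 called 79, no filter 133, the block 2 and the numbered block 15. Of any difference among the 3 genotypes (26), the counts were 196, 270 and 55 with DESeq2, no filter and the block. The overlap of the mutants against wt (15) was 48, 55, 25, 6 and 8 with DESeq2, no filter, the block, the numbered block and only 2 genotypes, and 5 with the erythroid covariate. Lists called fell to 4 in d9-20 vs wt (10) and 2 between the mutants (13) with the erythroid covariate, which absorbs a share of the same genes. With each library left out, the counts were 6 to 93, 10 to 33, 0 to 4 (mutants) and 10 to 62 (any difference), the overlap 5 to 25, and the lists 4 to 9 in d28-30 vs wt (5) and 6 to 14 between the mutants. Apart from fewer libraries in these fits, the cause was not tested. Single genes lost their call in 138 cases, gained it in 20 and kept their side in 1042. Of 20 settings, the call of Slc38a8 was lost in 10 in d9-20 and 8 in d28-30, and in d28-30 that of Fam129c in 10 and of Zfp868 in 7, and without wt replicate 2 or wt replicate 3 each of these 4 calls was lost. For lists these numbers were 77, 56 and 1748, and no called gene or list was called in the opposite direction. Some values changed sign between settings, among them the medians of EBF factors in d9-20 and of roof plate and multiciliation in d28-30. The block ended the calls of EBF factors (adjusted p = 0.0747) and immediate early genes (0.0511) between the mutants and made Gm7809 and Zfp868 pass there (both 0.0344). In all settings Gmnc passed in both mutants, with adjusted p from 2.63e-12 to 0.0384 in d9-20 and from 5.52e-16 to 0.00903 in d28-30, as did Coch. DESeq2 gave no adjusted p for 1523 genes in d9-20 vs wt and has no list test.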

Other observations

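The single genes given here were chosen after their values were seen. Collagen type I was lower in the mutants without passing the threshold. Col1a1, a main product of mesenchyme and bone-forming cells, was at 28.8 ± 9.22 CPM in d9-20 and 32.9 ± 5.28 CPM in d28-30 against 83 ± 31 CPM in wt (SD, n = 3), with log2 fold changes of -1.52 ± 0.27 (adjusted p = 0.0664, and 0.00289 adjusted over the list alone) and -1.34 ± 0.27 (adjusted p = 0.128, and 0.00771 adjusted over the list alone). The list of cranial and paraxial mesenchyme to which it belongs was not called (20 members tested, adjusted p = 0.635 in d9-20 and 0.841 in d28-30). Adjusted over the list alone, 2 members were higher and 2 lower in d9-20, and 2 lower in d28-30, while 0 passed over all genes tested.

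Genes of the primary cilium, among them genes mutated in Joubert syndrome, stayed near their wt levels. Of 26 tested, 0 passed in either mutant over all genes tested or adjusted over the list alone, with medians of -0.02 in d9-20 (adjusted p = 0.870) and 0.04 in d28-30 (adjusted p = 0.758). In the DNA damage response and repair list 0 of 27 passed either way (adjusted p = 0.568 and 0.954). Among p53 targets, Pmaip1 rose, and the list of 25 was not called (adjusted p = 0.176 and 0.193). Ttr, the main secreted product of the mature choroid plexus, had at most 9 counts in any library.

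Fgfbp3 and Ide lie in a segment whose copy number varies among C57BL/6J mice. Fgfbp3 was at 15.1 ± 0.307 CPM in wt, 12.3 ± 0.646 CPM in d9-20 and 18.2 ± 0.669 CPM in d28-30 (SD, n = 3), and Ide at 114 ± 8.01, 113 ± 4.47 and 125 ± 20.9 CPM.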
